A study of Homo sapiens with 6 samples.

How the data were processed

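The samples were 6 RNA-seq libraries of THP-1, an established human monocytic leukaemia cell line used as a model of monocytes. Per the labels, cells were controls or were given recombinant human interleukin-6 (IL-6), and total RNA was collected at 6, 24 and 48 h, with 1 library for each combination of agent and time. Per the labels' protocols, total RNA was amplified with the SMART-Seq low-input kit, which primes on poly(A) tails and makes full-length cDNA by PCR, and the cDNA was fragmented and tagged with Nextera XT. Neither step marks the strand of origin, so reads of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes the genome build was GRCh38 (hg38). The aligner, the counting program, the annotation release and the authors' normalization are not given in the sources used here.

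Each deposited table holds 60325 gene rows and 1 value per gene on a log2 scale, under the title of a processed signal per the file headers. The mean of each gene's deposited log2 values over the libraries that have a value is 0, to within 1.8e-07, so the authors centred every gene and the tables no longer hold absolute expression levels. A log2 difference of 1 between 2 libraries is a 2-fold difference. A value was listed in all 6 libraries for 17388 genes, in 1 to 5 libraries for 12319 genes and in no library for 30618 genes. These tables hold no read counts, so the sequencing depth is unknown, and no interval for counting error or detection limit is given.

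The level of most genes could be recovered in part. After 1 offset per library was removed, the values of a gene stood in ratios of whole numbers, as they would if length-normalised values rounded to a fixed step had been divided by 1 factor per library. The step was taken as 0.001, which sets an arbitrary unit. Matching within relative tolerances of 2e-06 for up to 5000 steps and 6e-07 above that recovered a level for 15596 genes, and for a further 100 genes with a library at a floor of 0.01, together 90.3% of those with 6 values. No level was recovered for the other 1692 genes, which were treated as high, as the range that could be matched ended at 100. These genes passed every level filter. Genes with libraries at the floor can also go unmatched, so some of the 1692 may be low. Of 2000 decoy genes, real genes with each value shifted at random by a small amount, 141 were matched by accident. The lowest mean level among them was 37.1. On 500 simulated genes, 455 were recovered correctly, 6 wrongly and 39 not at all, and each of the 39 exceeded 100 in at least 1 library. These levels served to filter genes, to set the variance trend, to match random gene lists and genes on level, to compare level classes and, in alternatives, to add a pseudocount.

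The plan fixed before the data were examined foresaw a count model with a fallback to limma on log2(value + 1). As the deposited values are already log2 values without a pseudocount, limma 3.58.1 in R 4.3.3 was applied to them directly, and log2(level + 1) on the recovered levels became an alternative. The linear model held time point and agent, over all 6 libraries, for the 13527 genes with 6 values and a mean level of at least 1. Residual variances were shrunk by robust empirical Bayes with a trend on the recovered level, with a median prior of 8.06 degrees of freedom beside 2 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The IL-6 effect is the difference between IL-6 and control over 3 time-matched pairs. Its error includes any change of the effect with time, because no condition was repeated. Nothing in the labels says that the 3 pairs came from separate cultures, so the p-values measure only the spread between these libraries. One gene with the value 0 in all 6 libraries has no residual variance and was kept. The change over culture time was the contrast of 24 h and of 48 h with 6 h, each time point having 1 control and 1 IL-6 library. A further model asked whether the IL-6 effect at 6 h differed from its mean at 24 and 48 h, with 1 residual degree of freedom. At single time points only ratios of 2 libraries were computed, without a p-value, for genes with a mean level of at least 10 over the 2 libraries.

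For gene groups, 36 lists were fixed before the data were examined, covering IL-6 signalling, inflammation, monocyte and macrophage functions, proliferation, metabolism, stress responses, housekeeping genes and markers of other cell types. The 32 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over the lists. The same test for culture time was added after the data were seen. At single time points the median ratio of a list was placed among the medians of 10000 random lists of the same size drawn from the same level bins. Symbols were matched through older names where needed.

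The models were tested on simulated data, in 5 simulations with 200 changed genes each among the 13527. With variances drawn from the fitted prior, the IL-6 comparison recovered 54.0% of genes changed by 1 on the log2 scale and 90.4% of those changed by 2, and 4.50% of its calls were false. The comparison of 48 h with 6 h recovered 34.8% and 76.0%, with 5.62% false calls. The comparison of the 6 h effect with the later effects recovered 2.60% and 35.4%, with 7.77% false calls. With the variances estimated for each real gene in place of the prior, false calls made up 10.8%, 13.6% and 29.5% of calls in these 3 comparisons, above the nominal rate.

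Genes were named by a rule fixed before the data were examined, whose minimum levels were planned for scaled read counts and were applied here to the recovered level. For the IL-6 effect it takes the 12 largest and 12 smallest log2 fold changes among genes past the threshold with a mean level of at least 5 and the same direction in all 3 pairs, or all that pass. For single time points it takes the 10 highest and 10 lowest ratios. For 48 h against 6 h it takes the 8 highest and 8 lowest log2 fold changes past the threshold at a level of at least 10. For the early against the late effect it takes the 6 smallest p-values of each sign, and for each list up to 4 members with the smallest p and any that pass. List members named for culture time have the smallest p for that change, a choice made after the data were seen. IL6, IL6R, IL6ST, STAT3, SOCS3, JAK1, PIM1, BCL3, CCL2 and MMP9 are named in every case. Genes known only by an identifier or a clone name are counted and not named, and values of 1 further gene are not reported here. Alternatives covered the scaling of libraries, the filter, the pseudocount, the empirical Bayes settings, the time term, the threshold and the omission of each time-matched pair or library. Coordinates are those of the deposited tables on GRCh38.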

Results

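Gene expression was measured by RNA-seq in THP-1 cells cultured with or without recombinant human IL-6 for 6, 24 and 48 h. The series design states the aim as finding the expression changes that IL-6 brings about in these cells, in a study of lung monocytes carrying the IL-6 receptor in chronic obstructive pulmonary disease. Each of the 6 conditions had 1 library, and no condition was repeated. A value was listed for 22000, 23108 and 22472 genes in the control libraries of 6, 24 and 48 h, and for 22333, 22733 and 22209 genes in the matching IL-6 libraries. The values are log2 values centred on each gene by the authors, the depth in reads is unknown, and 13527 genes entered the tests. Levels are in an arbitrary unit recovered from the deposited values, with the smallest step taken as 0.001.

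IL-6 raised the expression of a small set of genes over the 3 time-matched pairs, with the same direction at each time point. PIM1, a serine/threonine kinase gene known as a STAT3 target, rose by a log2 fold change of 2.67 ± 0.18 (limma SE, 3 pairs), or 6.36-fold. Its ratios were 2.15 at 6 h, 2.76 at 24 h and 3.09 at 48 h, with an SD of 0.48. The values after ± here and below are limma SEs with shrunken variances, and can be smaller than the spread of the ratios implies. BCL3, which encodes a nuclear IκB protein, rose by 2.48 ± 0.15, and its 3 ratios lay between 2.41 and 2.62. ANXA3, an annexin gene, rose by 2.62 ± 0.19, and CCL2, which encodes a chemokine that attracts monocytes, by 2.02 ± 0.15. The adjusted p-values from limma were 0.000139 for BCL3 and 0.000229 for each of PIM1, ANXA3 and CCL2. STAT3 itself, the transcription factor activated by the IL-6 receptor, was higher by 0.78 ± 0.12 (limma adjusted p = 0.0283), with ratios of 0.83, 0.54 and 0.97.

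In all, 31 genes were higher and 1 was lower with IL-6 over the 3 pairs at an adjusted p under 0.05, and 27 of the 31 are annotated as protein-coding. At an unadjusted p under 0.05 the balance was the other way, with 501 genes higher and 713 lower, and with equal library medians 637 were higher and 556 lower. The 32 genes had the same direction in all 3 pairs, which the test favours. Besides the genes above, the largest increases past the threshold at a level of at least 5 were in VCAN, which encodes the proteoglycan versican (2.03 ± 0.26), S100A8, a subunit of calprotectin (1.78 ± 0.18), and HSD11B1, whose enzyme regenerates active glucocorticoid (1.74 ± 0.16). They were followed by TMEM176A (1.48 ± 0.23), PARP9 (1.44 ± 0.20), LAP3, a leucine aminopeptidase gene (1.43 ± 0.11), POU2F2, which encodes the transcription factor OCT2 (1.42 ± 0.23), and CYP1B1, a cytochrome P450 gene (1.40 ± 0.20). No level was recovered for S100A8, HSD11B1 and LAP3, nor for METTL7B, FCGR1A and FCGR1B below. Such genes were treated as high, which lets them pass the level filter and sets their place in the variance trend. AKAP7, which encodes an A-kinase anchoring protein, was the gene that fell, by 1.34 ± 0.20 on the log2 scale (limma adjusted p = 0.0277), with ratios of -0.96, -1.60 and -1.46. Several further genes that passed lie outside the naming rule and were picked after their values were seen. Among these, the formyl peptide receptor gene FPR1 rose by 2.50 ± 0.31, the prostaglandin E2 receptor gene PTGER3 by 2.98 ± 0.33 and DEPP1 by 3.31 ± 0.38, all at mean levels under 5, and METTL7B rose by 1.32 ± 0.11. FCGR1A (0.65 ± 0.10), FCGR1B (1.22 ± 0.10) and FCGR1CP (1.19 ± 0.16), the Fcγ receptor I gene and its near-identical copies, also passed, and their values are uncertain because reads can be shared among the 3.

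**Figure D1:**
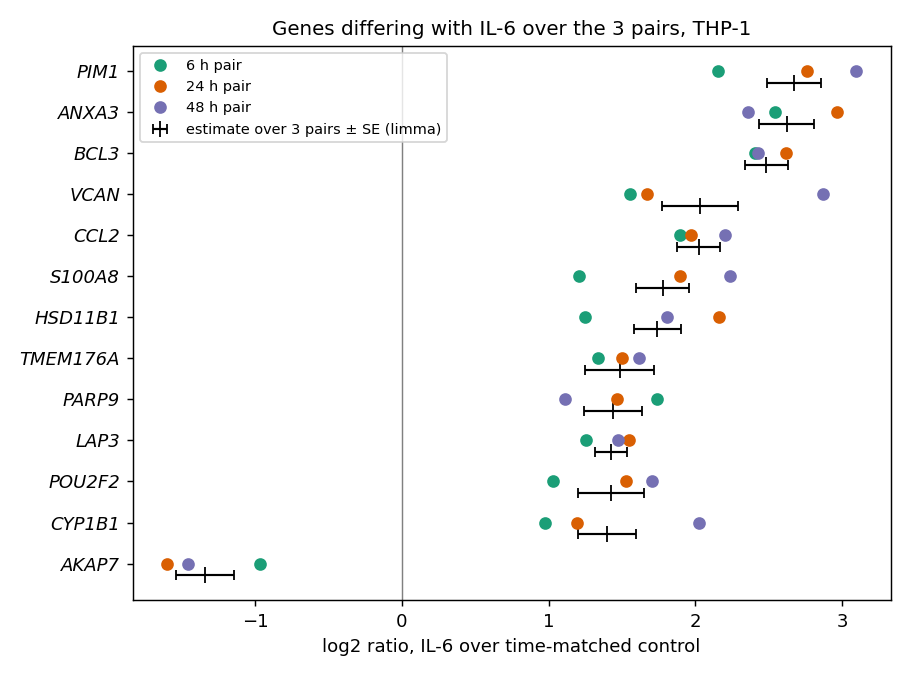
Log2 ratio of IL-6 over time-matched control (x axis) for the 12 genes raised and the 1 gene lowered by IL-6 that the naming rule takes. Coloured points are the ratios of the 6, 24 and 48 h pairs, and black bars the limma estimate over 3 pairs ± SE; PIM1, ANXA3 and BCL3 lie above 2 in every pair, and AKAP7 lies below 0 in every pair.

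In the deposited tables PIM1 (ENSG00000137193.14) lies on chromosome 6 from 37170152 to 37175428, BCL3 (ENSG00000069399.15) on chromosome 19 from 44747705 to 44760044 and ANXA3 (ENSG00000138772.13) on chromosome 4 from 78551747 to 78610451. CCL2 (ENSG00000108691.9) lies on chromosome 17 from 34255218 to 34257203, STAT3 (ENSG00000168610.16) on chromosome 17 from 42313324 to 42388540 and AKAP7 (ENSG00000118507.18) on chromosome 6 from 131135467 to 131283535, all on GRCh38. The values cover whole genes. Mean levels over the 6 libraries were 24.0 for PIM1, 20.3 for BCL3, 12.1 for ANXA3, 22.6 for CCL2 and 10.6 for AKAP7, and no level was recovered for STAT3.

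Without the variance trend no gene passed (1083 genes at an unadjusted p under 0.05, against 1214 with the trend), and non-robust empirical Bayes left 12 genes higher and 0 lower. Leaving out the 6, 24 or 48 h pair gave 81, 15 or 25 genes higher and 35, 1 or 5 lower, and ANXA3, BCL3, CCL2, FCGR1B, LAP3, METTL7B, PIM1 and PTGER3 were among the 9 genes called in each of those 3 fits.

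Of the components of the IL-6 receptor and of JAK-STAT signalling, 1 of 15 tested members, STAT3, passed in the IL-6 comparison, also when adjusted over the list alone. The receptor gene IL6R had a log2 difference of -0.28 ± 0.12 (limma adjusted p = 0.545), the co-receptor gene IL6ST of -0.04 ± 0.19 (limma adjusted p = 0.971) and JAK1 of -0.20 ± 0.13 (limma adjusted p = 0.726), none of them past the threshold. No value was listed for IL6 in any library. PIAS3 (-0.53 ± 0.21) and ADAM10 (-0.27 ± 0.12) did not pass either.

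Known STAT3 targets and feedback genes formed the list with the most genes past the threshold for IL-6. Of 32 tested members 4 rose (BCL3, PIM1, STAT3 and FCGR1A) and none fell, 12 rose and 0 fell when adjusted over the list alone, and 23 had a positive estimate. SOCS3, the feedback inhibitor of IL-6 signalling, had the high estimate of 2.54 ± 0.48 at a mean level of 2.75, with ratios of 2.16, 1.39 and 4.06, and did not pass over all genes (limma adjusted p = 0.117). The list as a whole was higher than other genes by camera (adjusted p = 1.45e-09 at the preset correlation), a call lost with an estimated correlation (adjusted p = 0.970).

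In the integrated stress and amino acid response list 23 of 24 members had a positive estimate, with a median log2 difference of 0.39. CHAC1, a glutathione-degrading enzyme gene induced by ATF4, rose by 1.31 ± 0.20, the 1 member past the threshold over all genes, whereas 16 rose and 0 fell when adjusted over the list alone. ATF5 (0.92 ± 0.19), the folate enzyme gene MTHFD2 (0.54 ± 0.12) and STC2 (2.08 ± 0.48) had positive estimates that did not pass over all genes. Camera gave an adjusted p of 6.48e-12 at the preset correlation and an adjusted p of 0.970 with an estimated correlation.

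Of 8 tested genes of MHC class II presentation none passed over all genes, 4 were lower when adjusted over the list alone, and all 8 had a negative estimate. The list was lower by camera at the preset correlation alone (adjusted p = 0.00599), and not with an estimated correlation (adjusted p = 0.970) or by fry (adjusted p = 0.322). HLA-DQB1 had an estimate of -0.47 ± 0.14, HLA-DMA of -0.47 ± 0.16 and HLA-DRA of -0.37 ± 0.13. HLA genes are polymorphic and alike in sequence, so single members are uncertain. The camera call was lost without the 48 h pair (adjusted p = 0.0654).

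At the preset correlation 7 further lists were higher by camera. These were immediate early genes (adjusted p = 0.00154; 0 of 14 members passed, with FOSL1 at 0.51 ± 0.18 and JUNB at 0.44 ± 0.16), glycolysis and hypoxia (0.00154; 0 of 25 passed and 2 rose when adjusted over the list alone, with the glucose transporter gene SLC2A3 at 2.22 ± 0.35), and MYC and ribosome biogenesis (0.0260; 0 of 21). Cholesterol synthesis and uptake (camera adjusted p = 0.0275, 0 of 22 passed) and interferon-stimulated genes (0.0489, 1 of 28, IFITM1 at 1.25 ± 0.18) were also higher. Of the interferon-stimulated genes 17 had a positive estimate, and 4 rose and 1 fell when adjusted over the list alone. The others were inflammatory cytokines and chemokines (0.0489, 1 of 12, CCL2) and the NRF2 oxidative stress response (0.0489, 0 of 17, with the haem oxygenase gene HMOX1 at 2.42 ± 0.49). When adjusted over the list alone, 3 and 2 of their members rose and 0 fell. With an estimated correlation no list passed for the IL-6 effect, each with a camera adjusted p of at least 0.970. That test has only 2 residual degrees of freedom. For immediate early genes the estimated correlation, 0.00736, was below the preset 0.01, yet the unadjusted camera p was 0.0632 against 0.000192. For this list the lost call therefore need not mean that the members vary together. The estimate was also below 0.01 for inflammatory genes (-0.00120). In every other called list it was higher, from 0.0646 for STAT3 targets to 0.596 for the stress and amino acid response list. It was 0.583 for MYC and ribosome biogenesis and 0.439 for glycolysis and hypoxia. The preset p-values of those lists can therefore be too small. Leaving out the 48 h pair ended the camera call of each of these 7 lists except MYC and ribosome biogenesis (adjusted p = 0.00804). Leaving out the 24 h pair ended that of interferon-stimulated genes (0.214), inflammatory genes (0.0509) and cholesterol genes (0.0509) by camera adjusted p, and leaving out the 6 h pair that of MYC and ribosome biogenesis (0.835).

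The remaining 22 tested lists did not pass by camera for the IL-6 effect. Among monocyte and macrophage genes, S100A8 and FCGR1A rose, 2 of 25 tested members and 3 when adjusted over the list alone, while the list median was -0.07 and its mean 0.34 (camera adjusted p = 0.288, upward). S100A9, the partner of S100A8, had an estimate of 1.80 ± 0.28 that did not pass (limma adjusted p = 0.205), and LYZ one of -0.27 ± 0.12. No member passed over all genes in the lists of matrix proteases and inhibitors (5 rose and 4 fell when adjusted over the list alone), acute phase proteins (2 rose), MHC class I presentation, the phagocyte oxidase and granules (1 rose and 2 fell), complement, alternatively activated macrophages (2 rose), NF-κB feedback, S-phase, mitosis or histones. The same held for ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, LXR targets, the unfolded protein response, heat shock, p53 targets (1 rose), the BCL2 family (1 rose and 1 fell), iron handling (1 rose and 1 fell) and housekeeping genes. Counts in brackets are adjusted over the list alone, and are 0 where none is given. Such counts, here and in the other paragraphs, are not corrected for the 36 lists examined. MMP9 had an estimate of 0.83 ± 0.60, with a ratio of 2.76 at 48 h and of -0.23 and -0.06 earlier. In 8 lists, the monocyte and macrophage list among them, the median, the mean and the camera direction did not share a sign. Markers of other cell types were mostly below the level filter: 2 of 14 T and NK cell markers, 2 of 9 B cell markers, 1 of 11 erythroid and platelet markers and 1 of 15 epithelial and fibroblast markers were tested, and none passed over all genes for the IL-6 effect. The 2 T and NK cell markers, NKG7 (0.65 ± 0.15) and IL7R (3.09 ± 0.76), had positive estimates that passed only when adjusted over these 2 genes alone, which is hardly an adjustment.

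At single time points, 78 genes at 6 h, 137 at 24 h and 127 at 48 h were at least 2-fold apart between IL-6 and control, of 7319, 7705 and 7632 genes at a mean level of at least 10. With 1 library per condition these ratios have no replicate check. More were higher than lower at 6 h (56 against 22) and 48 h (89 against 38), and at 24 h the 2 directions were alike (70 against 67). For scale, the control libraries of 24 and 6 h differed by at least 2-fold at 210 genes, those of 48 and 6 h at 153 and those of 48 and 24 h at 106.

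PIM1, BCL3 and ANXA3 were among the 10 highest ratios at 24 h, with HSD11B1 (2.16), S100A9 (2.15), the calgranulin gene S100A12 (2.49) and the clusterin gene CLU (2.68). At 48 h PIM1 (3.09), CLU (3.64) and S100A12 (3.16) were again among the 10 highest, together with CD14, the monocyte co-receptor for lipopolysaccharide, at 3.76. The ratio of CD14 was 0.71 at 6 h and 1.74 at 24 h. Other names at the extremes had ratios that differed between time points. GUCY1A2 was at 4.42 at 6 h, -4.51 at 24 h and -2.99 at 48 h, IQCH was at -5.91 at 24 h, -0.03 at 6 h and 0.15 at 48 h, and DKK3 went from -3.21 at 6 h to 4.16 at 48 h. The highest ratio at 6 h was that of the histone gene H2BC15, at 6.24, followed by 2.26 at 24 h and 0.70 at 48 h. Among the lowest were RCOR2 (-3.74) and ESRP2 (-3.68) at 6 h, MYH7B (-3.12) at 24 h, and SLC35F1 (-4.40), IL18BP (-1.32) and AKAP7 (-1.46) at 48 h. MYH7B had equal values in the IL-6 and control libraries of 48 h, as at the floor, so its level is doubtful.

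Of 7591 genes with a mean level of at least 10 over all libraries, 13 were at least 2-fold apart in the same direction at all 3 time points, and all 13 were higher with IL-6. They were PIM1, BCL3, ANXA3, CCL2, VCAN, S100A8, HSD11B1, LAP3, METTL7B, FCGR1B, FCGR1CP, SERPINA1 and SPTBN5. Of the 13, 5 had no recovered level and were treated as high. Genes 2-fold apart at all 3 times with 1 of the 3 signs opposite numbered 6 for 6 h, 3 for 24 h and 5 for 48 h. SERPINA1, which encodes the elastase inhibitor α1-antitrypsin, had ratios of 1.04, 1.39 and 2.98. SERPINA1 and SPTBN5 did not pass in the pooled test (limma adjusted p = 0.338 and 0.0558).

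Across genes, the log2 ratios of 6 and 24 h had a Pearson correlation of 0.26 (Spearman 0.35), those of 24 and 48 h of 0.16 (0.03) and those of 6 and 48 h of 0.03 (0.04), over the same 7591 genes, which are not independent replicates. The signs were the same in 62.5% of genes for 6 and 24 h and in 50.5% for each of the other pairs of time points. No library is shared between the pairs.

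**Figure D2:**
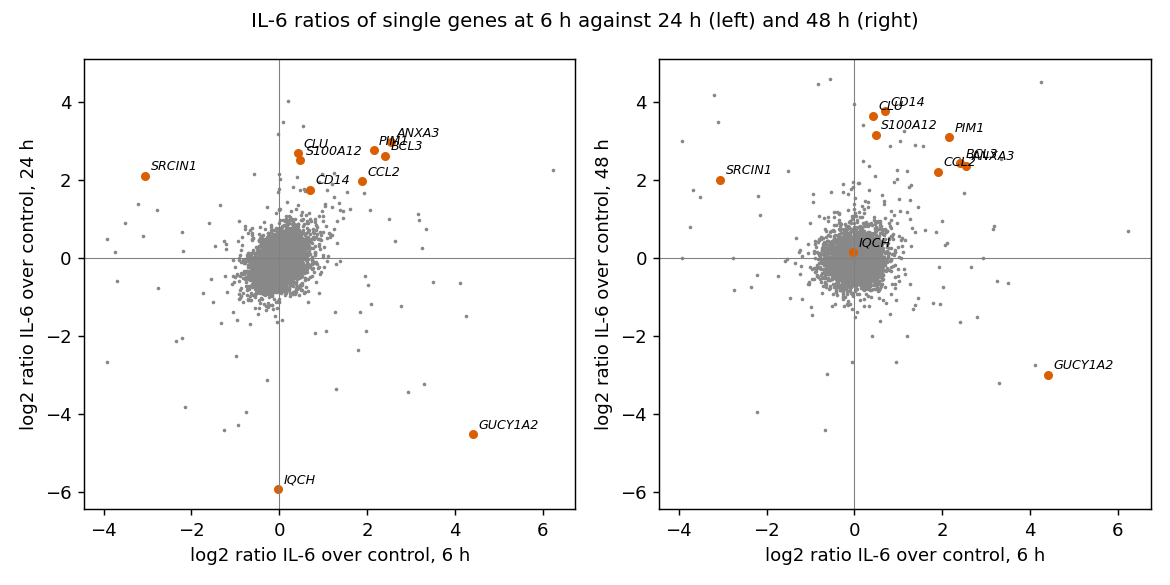
Log2 ratios of IL-6 over control of single genes with a mean level of at least 10, at 6 h (x axes) against 24 h (left) and 48 h (right), with 1 library per condition. PIM1, BCL3, ANXA3 and CCL2 lie high on both axes, CLU, S100A12 and CD14 lie high mainly on the later axis, and GUCY1A2 changes sign between 6 h and the later times.

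Of the 32 lists, 11 at 6 h, 11 at 24 h and 15 at 48 h had a median log2 ratio outside the central 95% of random lists of matched level. For STAT3 targets the median log2 ratio was 0.47 at 6 h, 0.12 at 24 h and 0.46 at 48 h, at the 100th, 98.8th and 100th percentile of the random lists, and immediate early genes stood at 0.26 (percentile 99.1), 0.26 (99.4) and 0.33 (99.9). The stress and amino acid response list stood at 0.17 (percentile 99.1), 0.52 (100) and 0.56 (100). Interferon-stimulated genes were at -0.19 (percentile 0.43) at 6 h, 0.16 (98.5) at 24 h and 0.26 (100) at 48 h. Monocyte and macrophage genes were at -0.03 (11.8), -0.29 (0.17) and 0.29 (100). MYC and ribosome biogenesis genes were at 0.30 at 6 h (percentile 100), 0.01 at 24 h (64.0) and -0.03 at 48 h (61.7). MHC class II genes were at -0.21 (2.19), -0.46 (0.37) and -0.29 (1.82). These percentiles describe the 2 libraries of each time point. The random lists hold unrelated genes, whereas members of a list can vary together between 2 libraries, so the percentiles are not chance values.

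The effect of IL-6 at 6 h was compared with the later effect in a model with 1 residual degree of freedom. The effect at 6 h rests on 1 pair, so its own spread was not measured. The error in this model comes from how far apart the later ratios of a gene lie, after shrinkage of variances. The model therefore cannot decide whether the effect of a gene at 6 h differed, and only the sizes of the differences are given here. S100A12 had a ratio of 0.48 at 6 h and of 2.49 and 3.16 later, a difference of -2.34. CLU had a ratio of 0.42 at 6 h and of 2.68 and 3.64 later, a difference of -2.74. The other genes that the naming rule takes were SRCIN1 (-5.11), PP2D1 (-4.75), RCOR2 (-4.21) and UBAP1L (-3.51) among those lower at 6 h. Those higher at 6 h were LINC02067 (4.14), SLC5A10 (3.42), SLC3A1 (2.75), RPS26P19 (2.77), POTEG (2.55) and TTYH1 (2.23). RPS26P19 and POTEG belong to families of near-identical copies and are uncertain. The number of genes called by this model changed with the scaling of the libraries and is given below.

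More genes passed for culture time than for IL-6. The contrast averages control and IL-6 libraries, so it does not part a change with time from one that depends on IL-6. Against 6 h and without a test, the control libraries alone were 2-fold apart at 210 genes at 24 h and 153 at 48 h. In the IL-6 libraries alone these counts were 223 and 462. At 24 h against 6 h, over control and IL-6 libraries together, 18 of 22 tested genes of cholesterol synthesis and uptake rose, 0 fell, and 21 rose when adjusted over the list alone, with a median log2 change of 1.15. The camera call of this list at 24 h was lost with an estimated correlation (adjusted p = 0.599), as were those of the next 3 lists. That camera test has only 2 residual degrees of freedom, and 0.599 was its lowest adjusted p for any list. A call lost there does not count against a change. LSS rose by 1.54 ± 0.14, MSMO1 by 1.39 ± 0.14 and INSIG1 by 1.32 ± 0.13, each with a limma adjusted p of 0.00174. Of 22 mitotic genes (adjusted p = 0.599 with an estimated correlation) 13 rose over all genes and 21 when adjusted over the list alone, among them CCNB1 (1.52 ± 0.13), CCNB2 (1.31 ± 0.13), CENPF (1.29 ± 0.14) and PLK1 (1.35 ± 0.16). Of 22 S-phase and replication genes (adjusted p = 0.599 with an estimated correlation) 5 fell over all genes and 18 when adjusted over the list alone, with PCNA at -0.87 ± 0.15, E2F1 at -0.79 ± 0.15 and CDC6 at -0.74 ± 0.15. Of 25 glycolysis and hypoxia genes (adjusted p = 0.599 with an estimated correlation) 8 rose, and 12 when adjusted over the list alone, with P4HA1 at 1.77 ± 0.17, VEGFA at 1.65 ± 0.22, NDRG1 at 1.82 ± 0.27 and BNIP3 at 1.72 ± 0.23. CDKN1A, the cell cycle inhibitor p21 and a p53 target, rose by 1.72 ± 0.19. Of 16 tested p53 targets 2 rose over all genes, 6 rose when adjusted over the list alone, and 0 fell. The camera call of that list (adjusted p = 0.00359) was lost with an estimated correlation (camera adjusted p = 0.599).

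At 48 h against 6 h the amino acid and integrated stress response list had the most calls, with 19 of 24 members higher and 0 lower, and 21 higher when adjusted over the list alone; at 24 h 8 had risen. Its camera call at 48 h was lost with an estimated correlation (adjusted p = 0.545), as were those of the interferon, cholesterol, oxidative phosphorylation and unfolded protein response lists. Here too that camera test has only 2 residual degrees of freedom, and 0.545 was its lowest adjusted p for any list. CHAC1 rose by 3.12 ± 0.24, the asparagine synthetase gene ASNS by 2.69 ± 0.27, the serine synthesis genes PHGDH by 2.45 ± 0.16 and PSAT1 by 2.11 ± 0.18 and SESN2 by 2.34 ± 0.29. The amino acid transporter gene SLC7A5 rose by 1.53 ± 0.12 and ATF4 by 1.28 ± 0.13. Of 28 interferon-stimulated genes (adjusted p = 0.545 with an estimated correlation) 10 rose over all genes and 22 when adjusted over the list alone, with MX1 at 2.14 ± 0.31 and IFI44 at 2.62 ± 0.36. At 24 h 4 of them had risen. Of 22 cholesterol genes (adjusted p = 0.553 with an estimated correlation) 7 were higher than at 6 h (18 when adjusted over the list alone), and of 22 mitotic genes 2, PLK1 (0.81 ± 0.16) and CCNB1 (0.65 ± 0.13). Of 21 nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.545 with an estimated correlation) 6 fell over all genes, and 11 fell and 1 rose when adjusted over the list alone, with NDUFA4 at -0.97 ± 0.16 and COX6C at -0.84 ± 0.16. Of 17 unfolded protein response genes (adjusted p = 0.545 with an estimated correlation) 6 fell, CRELD2 (-1.03 ± 0.13) and SDF2L1 (-1.01 ± 0.15) among them, and 3 rose, with HERPUD1 at 1.10 ± 0.14, against 7 and 3 when adjusted over the list alone.

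Among genes with a symbol and a level of at least 10, the other largest rises at 48 h were in the cytokine gene TNF (2.33 ± 0.23), JDP2 (2.26 ± 0.19) and SYTL1 (2.17 ± 0.23). The largest falls past the threshold among these genes were in the junctional adhesion molecule gene JAM3 (-3.42 ± 0.31), ZNF827 (-2.56 ± 0.32), LYZ, which encodes lysozyme (-1.78 ± 0.14), and the metallothionein gene MT1X (-1.62 ± 0.20). They were followed by CTNNAL1 (-1.39 ± 0.28), BOLA3 (-1.38 ± 0.19), the pseudogene RPS26P6 (-1.38 ± 0.25), which can share reads with its parent gene, and TPM2 (-1.36 ± 0.19). Of the 16 genes that the naming rule takes for 48 h, 6 were not called without the 48 h IL-6 library (ASNS, MX1, ZNF827, CTNNAL1, RPS26P6 and TPM2), and CTNNAL1 and RPS26P6 were not called without the 6 h IL-6 library either.

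**Figure D3:**
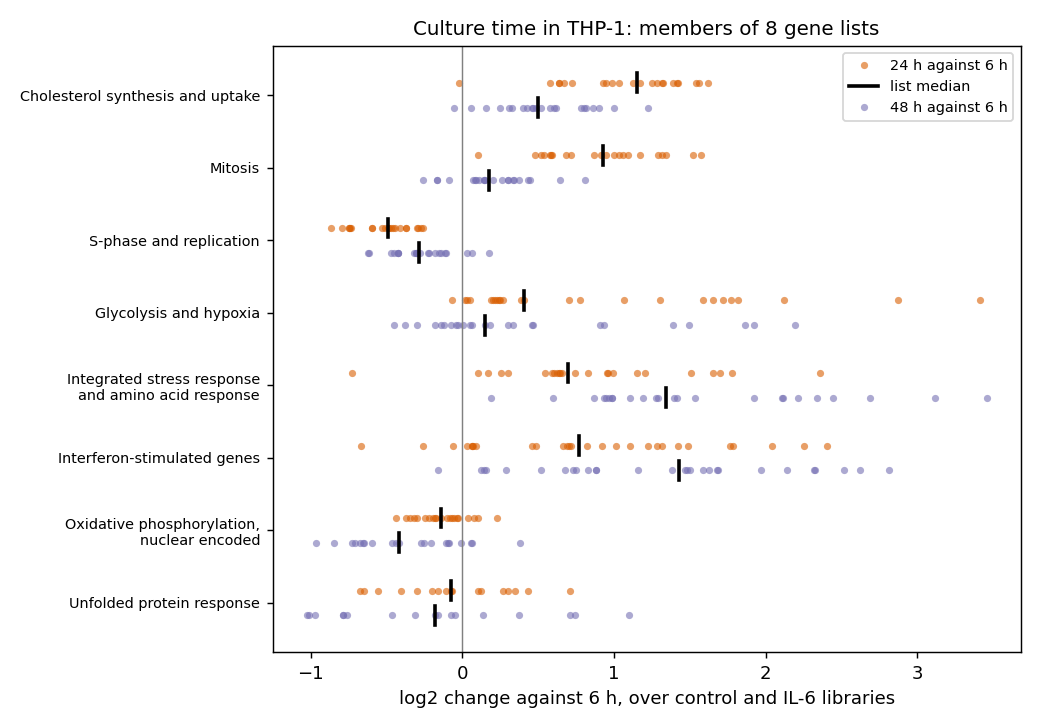
Log2 change against 6 h over control and IL-6 libraries (x axis) for the tested members of 8 gene lists, 1 point per gene, at 24 h (orange) and 48 h (purple); black bars mark list medians. The median of cholesterol genes was 1.15 at 24 h and 0.50 at 48 h, and that of the stress and amino acid response list 0.70 and 1.34.

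In total 257 genes changed at 24 h (217 higher, 40 lower) and 525 at 48 h (337 higher, 188 lower), in limma with an adjusted p under 0.05. The median of all tested genes was itself shifted by 0.11 at 24 h and 0.07 at 48 h, and with equal library medians the counts were 132 higher and 60 lower at 24 h, and 276 higher and 285 lower at 48 h. With the authors' library factors removed the medians were 0.10 and 0.17 and the counts 209 and 48 at 24 h, and 627 and 168 at 48 h. By camera at the preset correlation 12 lists passed at 24 h and 15 at 48 h, and 0 with an estimated correlation (adjusted p of at least 0.599 and 0.545). Without the variance trend no gene passed at either time, while 1917 and 2249 genes had an unadjusted p under 0.05. The 24 h count was 30 without the 24 h control, 55 without the 24 h IL-6 library and 549 without either 48 h library. The 48 h count was 1128 without the 48 h control, 171 without the 6 h IL-6 library and 114 without the 48 h IL-6 library.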

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

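The tests on genes apart at 1 time point and on the early effect were chosen after their results had been seen in part, and the splits of the libraries before. The model that set the 6 h pair apart called 32 genes for an IL-6 effect unlike its mean at 24 and 48 h. The effect at 6 h rests on 1 pair, so its own spread was not measured. Setting the 24 h pair apart in the same model called 9 genes and setting the 48 h pair apart 18, so the 6 h pair gave the highest number. A candidate explanation is that with 1 residual degree of freedom the 2 remaining pairs lie close together by coincidence in some genes. The values of 18 and 9 leave this open, since both are lower than 32 but 18 is not low enough to meet the bound set for excluding it, and in simulations with each gene's estimated variance 29.5% of calls were false. A later onset of part of the IL-6 response, as in S100A12 and CLU, remains open as well, because no time point was repeated.

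A second pattern is the number of genes at least 2-fold apart at 1 time point only, 135 of the 7591 genes at a level of at least 10. The share of such genes was 2.03% at levels of 10 to 100 and 0.887% among genes without a recovered level, which were treated as high. The ratio was 2.29 (95% interval 1.35 to 3.91), against a bound of 3. It cannot decide on low expression, because the class without a recovered level can hold genes with libraries at the floor. Low expression stays open. Outside the pattern, at levels of 1 to 10, the share was 23.2%, and this class was first used for the test, where it favoured low expression, and was replaced after its value had been seen. Uneven measurement without regard to IL-6 could be expected to spread the 4 libraries of the other 2 time points 2-fold in at least 50% of these genes, and they did in 62 of the 135, or 45.9% (95% exact binomial interval 37.3 to 54.7, genes taken as independent), against 7.30% of genes of matched level. The share lies under the bound of 50%, which taken alone would count against uneven measurement. Its interval includes 50%, a rule added after the share was seen, and the share lies well above the 7.30% of matched genes. Uneven measurement therefore stays open. A response to IL-6 limited to 1 time point was not tested and stays open too.

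The count of 31 genes higher with IL-6 was compared with the other splits of the 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05; 1 of the 10, the real one, gave as many genes, and the highest of the others called 3. For the 1 lower gene, 6 of the 10 splits gave as many in their smaller direction, the highest other being 3. In 6 of the other splits the contrast rests on 1 time-matched pair, because both libraries of the other time points fall in 1 group. Among the 4 splits that part each pair, the real one included, the highest other called 3 genes in its larger direction, and 2 gave as many as the 1 lower gene, the highest other being 1.

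Among genes left out of the tests because some libraries had no value, 83 had a value in all 3 IL-6 libraries and in no control library, against 80 in the 3 control libraries and in no IL-6 library. This met the criterion of a signal above the controls in data outside the main measurement by 3 genes. The other 18 sets of 3 libraries gave between 62 and 128 genes.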

How the results depend on the processing

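The scaling stand-ins, equal library medians and removal of the authors' library factors, the omission of the variance trend and the looser threshold for culture time were added after the data were seen. None of the 32 genes called for the IL-6 effect changed sign under any alternative run, but this was largely fixed in advance and is no support. All 32 had the same direction in the 3 pairs, so leaving out a pair could not reverse them. Nor could the filter, the pseudocount, the empirical Bayes settings, the time term or the threshold, which leaves only the scaling. Of these 32 genes, 32 were called with either pseudocount, 31 with equal medians, 30 with factors removed, 12 without the level filter, 12 with non-robust empirical Bayes, 4 without the time term and 0 without the trend. The cause of each change was not tested, except that leaving out a pair leaves 1 residual degree of freedom.

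Genes higher with IL-6 numbered 12 without the filter, 4 without the time term, 12 with non-robust empirical Bayes and 0 without the trend, and 15 to 81 on leaving out a pair. Genes lower numbered 3 with factors removed, 0 without the filter, 6 at a level of at least 10, 0 without the time term, 0 with non-robust empirical Bayes, and 0 without the trend. They numbered 4 with a pseudocount of 1, 6 at an adjusted p under 0.1, and 1 to 35 on leaving out a pair. At 24 h against 6 h, 144 genes changed without the filter, 145 with non-robust empirical Bayes, 0 without the trend (1917 at an unadjusted p under 0.05), 629 at an adjusted p under 0.1, and 30 to 549 on leaving out a library. At 48 h against 6 h the counts were 795 with factors removed, 262 without the filter, 244 with non-robust empirical Bayes, 0 without the trend (2249 unadjusted), 1170 at an adjusted p under 0.1, and 114 to 1128 on leaving out a library. The control libraries alone were 2-fold apart at 153 genes, and the IL-6 libraries alone at 462. At 24 h these counts were 210 and 223. A lone library left at a time point is assumed to vary like the others. The early against late comparison gave 21 genes with equal medians and 76 with factors removed.

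Genes apart at 6, 24 and 48 h numbered 332, 782 and 489 at 1.5-fold, 40, 54 and 50 at 3-fold, 801, 999 and 958 at a level of at least 1, 17, 31 and 30 at a level of at least 50, and 51, 58 and 64 with a pseudocount of 10. The mean correlation of the ratios between time points was 0.15, and 0.12 to 0.20 under its alternatives. The number of lists called for the IL-6 effect was 10, against 0 with an estimated correlation (0 unadjusted), 0 with fry (4 unadjusted) and 5 to 10 on leaving out a pair. The count models and the removal of mitochondrial transcripts before normalization were not run, for want of counts and of levels. No paired analysis was possible beyond the time-matched pairs because each condition has replicate 1 alone.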

Other observations

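The test of IL-6 against culture time was set before its value was seen, and the genes named first were chosen after theirs were. Several genes outside the pooled calls had higher ratios at 24 and 48 h than at 6 h, with 1 library per condition. HMOX1 had ratios of 0.82, 3.07 and 3.37 at 6, 24 and 48 h, at a mean level of 2.70, the lectin gene CLEC10A of 0.10, 3.07 and 2.98 at a mean level of 1.22, and the interleukin-7 receptor gene IL7R of 0.67, 4.33 and 4.25 at a mean level of 2.24. The chemokine gene CCL3 went the other way, from 2.03 at 6 h to 1.26 and 0.94. None of the 4 passed in the pooled test, with adjusted p-values from limma of 0.145 for HMOX1, 0.336 for CLEC10A, 0.315 for IL7R and 0.253 for CCL3. Nor did any of them pass in the test of the 6 h effect against its mean at 24 and 48 h. The difference was -2.40 for HMOX1, -2.92 for CLEC10A, -3.62 for IL7R and 0.93 for CCL3. The effect at 6 h rests on 1 pair, so its own spread was not measured and that test cannot decide on single genes. The NADPH oxidase gene NCF1, which has near-identical pseudogenes, had an estimate of -1.01 ± 0.18 (limma adjusted p = 0.0765), and the BH3-only gene BIK one of -0.58 ± 0.11 (limma adjusted p = 0.116).

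The stress and amino acid response list was higher with IL-6 and with culture time by camera at the preset correlation, and CHAC1 rose in both. With an estimated correlation, in a camera test with only 2 residual degrees of freedom, these calls were lost (adjusted p = 0.970 for IL-6, adjusted p = 0.599 at 24 h and adjusted p = 0.545 at 48 h). A hypothesis was that IL-6-treated cells lie further along the changes of culture time in general. Across the 13527 genes the IL-6 effect and the 48 h against 6 h change had a Pearson correlation of -0.0184 (Spearman -0.12). Of the 525 genes called for culture time, 45.9% had the same sign of IL-6 effect, where the hypothesis needed a correlation above 0.2 and at least 75%. Neither value reached its bound, so the IL-6 effect over all time points showed no general shift of that size along culture time. A later or smaller shift stays open. The 48 h IL-6 ratios shared their sign with those of 6 h, and of 24 h, in 50.5% of genes at a level of at least 10. The bounds may therefore have been out of reach. Between 48 h and 6 h, the IL-6 libraries alone were 2-fold apart at 462 genes and the control libraries alone at 153. The test did not weigh these counts. A shared change limited to amino acid response genes was not tested. Genes are not independent replicates, and the effects of IL-6 and of culture time are estimated from the same 6 libraries in a balanced design.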
